A study of Homo sapiens with 33 samples.

How the data were processed

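Bulk RNA sequencing was done on 33 head and neck squamous cell carcinomas, 25 de novo and 8 radiation-recurrent, with 1 tumor per patient. Per the labels' protocols, poly(A) RNA was made into stranded libraries with an Illumina TruSeq kit and read as pairs of 100 bases. The authors deposited 1 table of raw read counts per gene and tumor, made with FastQC, Trimmomatic, STAR and featureCounts on GRCh38, per the submitters' processing notes. Tool versions, the annotation release, the strand setting of the counting and the filter that left 17003 genes are not given in the sources used here. The deposited length in bases per gene was not used in any test. Tumors were grouped by their labels and named by group and a replicate number given in order, which pairs no tumors. The labels used here give no tumor site, viral status or batch.

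Gene identifiers were matched to GENCODE v29, which held 16955 of them, and coordinates, strand and exon overlap were taken from it on GRCh38. Exon overlap was counted only between genes of the deposited table. Overlap with other genes of GENCODE v29 was not seen, so a gene without a counted overlap may still have one. The start and end deposited with the counts spanned less than the deposited length for 16610 genes and were not used. XIST, TSIX and Y-linked genes (11 in all) were left out because the samples are human tumors. Of the 16992 genes kept, 1091 were removed by edgeR's filterByExpr by group (minimum count 10, minimum total 15), and 15901 were tested.

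Counts were scaled by TMM factors and compared with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust=TRUE, glmQLFTest), with no covariates and no fold minimum, and called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.778. Log2 fold changes are radiation-recurrent minus de novo, and each SE is the absolute log2 fold change divided by the square root of its F statistic. CPM are counts per M counts of the TMM-scaled library. On 5 simulated data sets of the real genes and library sizes, each with 200 changed genes among 15901, this comparison recovered 33.4, 69.3 and 87.5 percent of genes changed 2, 4 and 8 times, with 2.15 percent false among the calls. The simulated counts were drawn independently for each gene and library. They lack the links between genes and the kinds of library described below, so these rates may not hold for the real tumors.

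Gene lists for cell types, pathways and amplified regions (43 lists) were fixed before the data were examined, as were the groups, the tests and the first set of alternatives. A tumor's list score is the mean z-score of log2 CPM (prior count 2) over the tested members. Scores were compared by an exact two-sided permutation test over all 13884156 assignments and adjusted over 42 lists, since the erythrocyte list had 3 of its 8 members tested, under the minimum of 4, and was not scored. Intervals in the plot of lists are from 10000 bootstrap resamples. Genes named in the text were chosen by a rule: in each direction the 12 with the smallest p among those that passed, all where fewer passed, and the 5 with the smallest p where fewer than 5 passed, leaving out unnamed loci, pseudogenes and receptor segments. The rule adds the 2 members with the smallest p of each list described, and 10 genes given whatever their value. Which lists were described beyond their scores was decided after the scores were seen. A p-value adjusted over a list alone takes no account of that choice or of the other lists, so such passes are descriptive.

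Library measures were compared by exact permutation tests adjusted over 5 measures, spread by the mean of 1 minus Spearman's rho between tumors over the 1000 most variable genes, and principal components by exact permutation tests adjusted over 10. Permutations and components were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Alternatives were other scalings (RLE, upper quartile), filters, DESeq2 1.42.0, limma 3.58.1 (voom, camera, fry), Wilcoxon tests, list scores as covariates, 2 surrogate variables from sva 3.50.0, 500 or 3000 genes for spread and components, and leaving out each tumor in turn (for list scores each radiation-recurrent tumor). DESeq2 was run with its default settings, under which outlying counts of a gene can be replaced before the test. The kind of library and its mark of 1 percent of mitochondrial counts in MT-ND6 were found from the data, and every alternative that uses them, or that leaves out named de novo libraries, was added after seeing the data.

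Total counts per library, from 12312484 to 591671886, set the precision of low counts, and the p-values rest on the spread between tumors. A gene whose exons overlap another gene on the opposite strand, or that belongs to a family of similar sequences, has uncertain counts here.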

Results

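Head and neck squamous cell carcinoma is a cancer of the squamous lining of the mouth, throat and voice box. Bulk RNA sequencing measured gene expression in 33 such tumors, each labelled with a different patient. Of these, 25 had arisen de novo and 8 had grown back inside an earlier radiation field and were removed at salvage surgery, here called radiation-recurrent. The values are read counts for 17003 genes. Total counts ranged from 21399217 to 35596941 in the 8 radiation-recurrent libraries and from 20185326 to 35013662 in 23 de novo libraries, while de novo 3 held 12312484 and de novo 24 held 591671886.

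The libraries were of 2 kinds that the labels do not name. MT-ND6, a mitochondrial gene on the strand opposite to the other mitochondrial protein genes, took 1.44 to 3.31 percent of the mitochondrial counts in 7 libraries (de novo 3, 6, 11 and 24, and radiation-recurrent 2, 4 and 6) and 0.0149 to 0.151 percent in the other 26. CCDC152, whose exons lie opposite the abundant SELENOP transcript, had 74.8 to 90.5 counts per 100 SELENOP counts in the 7 libraries, against a median of 0.349 and a highest value of 54.2 in the 26. The 7 libraries held 3 of the 8 radiation-recurrent and 4 of the 25 de novo tumors (Fisher's exact test, two-sided, p = 0.320). Values within each kind are given for the genes past the threshold, the lists described and some others. Of 46 named genes, 1 turned direction among the 26 libraries, and of 44 with a value among the 7, 11 did.

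**Figure D1:**
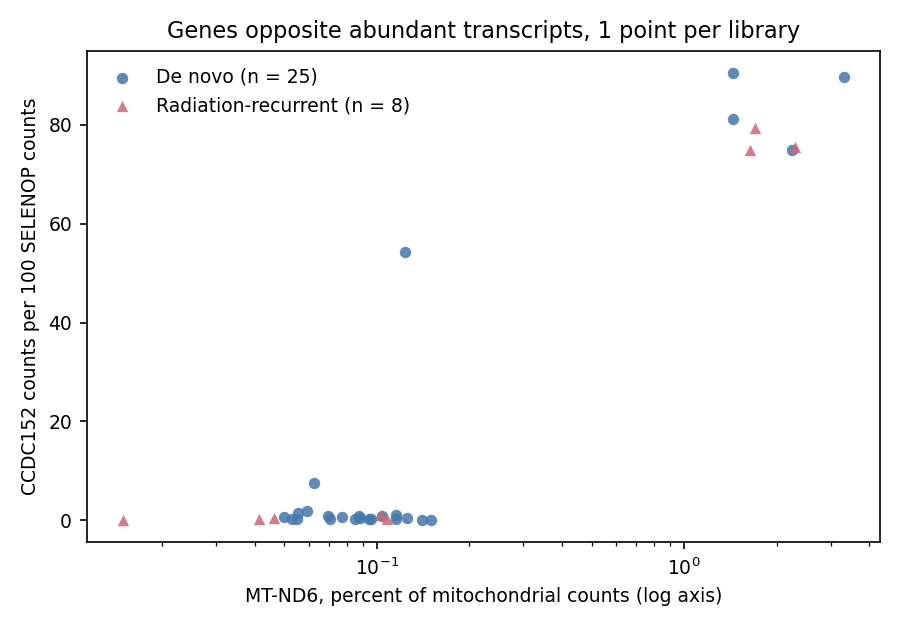
Counts of CCDC152 per 100 counts of SELENOP (vertical axis) against the percent of mitochondrial counts in MT-ND6 (horizontal log axis), 1 point per library, by tumor group. The 7 libraries at 1.44 percent or more lie at 74.8 to 90.5 on the vertical axis, and the highest of the other 26 lies at 54.2.

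The first comparison asked which genes differ between radiation-recurrent and de novo tumors. Of 15901 genes tested, 7 were higher in radiation-recurrent tumors and 0 were lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). They were NELL1, a secreted protein that promotes bone formation, ULBP1, a stress-induced ligand of the NKG2D receptor of killer lymphocytes, ODAPH, a protein of tooth enamel mineralization, DIRAS3, an imprinted Ras-family GTPase, RNF182, a ubiquitin ligase, STC1, a secreted glycoprotein hormone, and SCN9A, a voltage-gated sodium channel. In each of the 7, the SD over the radiation-recurrent tumors exceeded their mean, and each gene lost its call when its highest radiation-recurrent tumor was left out.

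NELL1 (ENSG00000165973.19, chromosome 11, 20669551 to 21575681, plus strand) averaged 24.4 ± 60.1 CPM (SD, n = 8) in radiation-recurrent and 0.224 ± 0.325 CPM (SD, n = 25) in de novo tumors, a log2 fold change of 6.68 (SE 0.96, edgeR adjusted p = 0.000700). Its highest value was in radiation-recurrent 3, with 4995 counts, and without that tumor the log2 fold change was 3.80 (edgeR adjusted p = 0.139). ULBP1 (ENSG00000111981.5, chromosome 6, 149964007 to 149973710, plus strand) averaged 23.4 ± 57.1 against 0.694 ± 0.745 CPM, a log2 fold change of 5.06 (SE 0.75, edgeR adjusted p = 0.000775), which became 2.21 without radiation-recurrent 7 (edgeR adjusted p = 0.470). ODAPH (ENSG00000174792.10, chromosome 4, 75556048 to 75565885, plus strand) averaged 9.11 ± 23.3 against 0.270 ± 0.291 CPM, a log2 fold change of 5.04 (SE 0.79, edgeR adjusted p = 0.00137), and 1.66 without radiation-recurrent 4 (edgeR adjusted p = 0.625). NELL1, ULBP1 and ODAPH each had 3 radiation-recurrent tumors above the highest de novo tumor.

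DIRAS3, RNF182 and STC1 were highest in the same tumor, radiation-recurrent 5, and each had 1 radiation-recurrent tumor above the highest de novo tumor. DIRAS3 (ENSG00000162595.7, chromosome 1, 68045896 to 68051631, minus strand) averaged 31.01 ± 81.6 against 1.22 ± 1.70 CPM, a log2 fold change of 4.66 (SE 0.75, edgeR adjusted p = 0.00191). RNF182 (ENSG00000180537.13, chromosome 6, 13924446 to 13980302, plus strand) averaged 9.25 ± 24.5 against 0.426 ± 0.669 CPM, a log2 fold change of 4.43 (SE 0.82, edgeR adjusted p = 0.0145). STC1 (ENSG00000159167.12, chromosome 8, 23841915 to 23854807, minus strand) averaged 203 ± 531 against 19.8 ± 17.8 CPM, a log2 fold change of 3.36 (SE 0.64, edgeR adjusted p = 0.0207). Without radiation-recurrent 5 the log2 fold changes were 0.84 for DIRAS3, 0.43 for RNF182 and −0.35 for STC1 (edgeR adjusted p = 0.976, 0.993 and 0.989), and in DESeq2 STC1 stood at −0.37. SCN9A (ENSG00000169432.16, chromosome 2, 166195185 to 166376001, minus strand) averaged 22.6 ± 51.03 against 2.06 ± 2.46 CPM, a log2 fold change of 3.45 (SE 0.68, edgeR adjusted p = 0.0332). SCN9A lost its call without radiation-recurrent 3 (log2 fold change 1.18, edgeR adjusted p = 0.960) and also without each of 12 de novo tumors in turn (1, 2, 3, 8, 9, 10, 13, 17, 20, 21, 22 and 24), with a highest edgeR adjusted p of 0.0589.

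**Figure D2:**
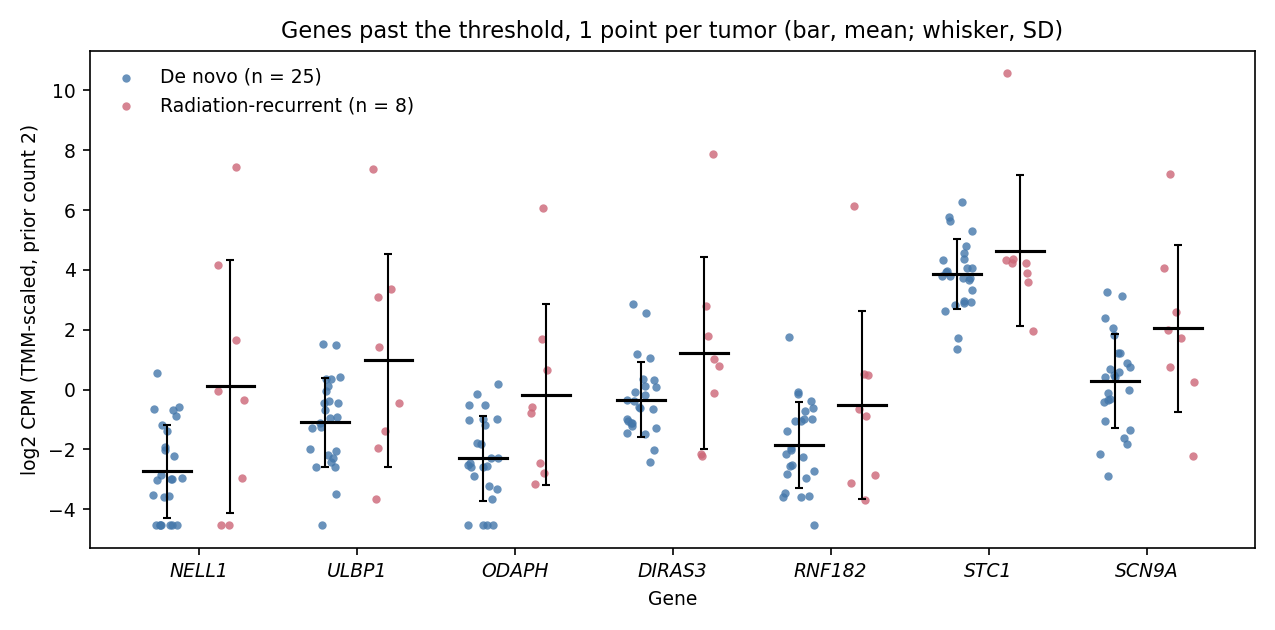
Log2 CPM (vertical axis, scaled by TMM factors, prior count 2) of the 7 genes past the threshold, 1 point per tumor, with bars at the group means and whiskers of 1 SD. In radiation-recurrent 5, STC1 stood at 10.57 while the next radiation-recurrent tumor stood at 4.36.

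Among the 26 libraries with a low MT-ND6 share (5 radiation-recurrent, 21 de novo), NELL1, ULBP1, DIRAS3, RNF182, STC1 and SCN9A passed with log2 fold changes of 7.30, 5.82, 5.31, 5.69, 4.16 and 4.04, and ODAPH did not (1.92, edgeR adjusted p = 0.316). Among the other 7 libraries (3 radiation-recurrent, 4 de novo), ULBP1 stood at 0.079, ODAPH at 5.52, DIRAS3 at 1.09, RNF182 at −2.42, STC1 at −0.85 and SCN9A at 0.16, none passed, and NELL1 had too few counts to be tested. The highest tumors of NELL1, ULBP1, DIRAS3, RNF182, STC1 and SCN9A were among the 26 libraries, and that of ODAPH among the 7. These values therefore cannot tell the kind of library from the place of single tumors. With the kind of library as a covariate, 5 of the 7 genes passed, while ODAPH (3.17, edgeR adjusted p = 0.260) and SCN9A (3.29, edgeR adjusted p = 0.0573) did not. With the skeletal muscle score as a covariate ODAPH (2.89, edgeR adjusted p = 0.194) and SCN9A (3.43, edgeR adjusted p = 0.0672) did not pass, and with the HPV-associated score 3 of the 7 passed. With the T cell, B cell and macrophage score as a covariate, 1 of the 7 passed, NELL1 (6.76, edgeR adjusted p = 0.00399), and the others stood at 2.97 for ULBP1 (edgeR adjusted p = 0.540), 5.01 for ODAPH (edgeR adjusted p = 0.187), 3.21 for DIRAS3 (edgeR adjusted p = 0.574), 3.09 for RNF182 (edgeR adjusted p = 0.620), 1.91 for STC1 (edgeR adjusted p = 0.744) and 3.40 for SCN9A (edgeR adjusted p = 0.108). The count of genes past the threshold was 38 among the 26 libraries, 0 among the 7 (1536 at an unadjusted p under 0.05 in edgeR), 10 with the covariate and 127 without de novo 3, 6, 11 and 24. Leaving out radiation-recurrent 1, 4 or 6 gave 14, 14 and 15 genes. At an unadjusted p under 0.05, edgeR gave 617 higher and 393 lower genes, where chance gives 795 in all, and 61 of 100 random splits of the 33 tumors, the real one included, gave as many. DESeq2 gave 543 higher and 831 lower genes at an unadjusted p under 0.05. Outlying counts can be replaced in its default run, so its results need not rest on the counts of all 33 tumors. DESeq2 called 7 higher and 14 lower genes, of which ULBP1 was shared and 0 belonged to the 13 lists described below. A further 5 of these genes belonged to lists described under other observations, and 2 to the 22 other lists there. By contrast, limma voom called 0 and the Wilcoxon rank-sum test called 0.

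No gene passed as lower in edgeR. The 5 with the smallest p were MOV10, an RNA helicase of antiviral defence, TNN, the matrix protein tenascin N, BCO1, which cleaves beta-carotene, GRP, gastrin-releasing peptide, and CCL21, a chemokine that draws T cells and dendritic cells. In each of these 5 genes, 0 of the 8 radiation-recurrent tumors lay above the de novo median. MOV10 (ENSG00000155363.18, chromosome 1, 112673141 to 112700746, plus strand) averaged 24.7 ± 10.2 CPM (SD, n = 8) against 55.2 ± 25.01 CPM (SD, n = 25), a log2 fold change of −1.16 (SE 0.27, edgeR adjusted p = 0.145). CCL21 (ENSG00000137077.8, chromosome 9, 34709005 to 34710124, minus strand) averaged 2.60 ± 3.14 against 38.1 ± 51.7 CPM, a log2 fold change of −3.87 (SE 1.13, edgeR adjusted p = 0.368). TNN, BCO1 and GRP had log2 fold changes of −2.89, −3.51 and −2.63 (edgeR adjusted p = 0.245, 0.353 and 0.362). DESeq2 called all 5 of these genes lower, with adjusted p of 0.00986 for MOV10, 0.00398 for TNN, 0.00843 for BCO1, 0.0297 for GRP and 0.00398 for CCL21. MOV10 also passed in edgeR without radiation-recurrent 6 (log2 fold change −1.36, edgeR adjusted p = 0.0438) and without de novo 3, 6, 11 and 24 (−1.15, edgeR adjusted p = 0.0379). The second setting leaves libraries with a high MT-ND6 share in the radiation-recurrent group alone. MOV10 did not pass with the kind of library as a covariate (−1.26, edgeR adjusted p = 0.103) or among the 26 libraries (edgeR adjusted p = 0.0599). The acyl-CoA thioesterase ACOT11, chosen after its values were seen, passed as lower among the 26 libraries (−1.20, edgeR adjusted p = 0.0350) and stood at −0.50 over all 33 and 0.074 among the 7. Among the 26 libraries MOV10 stood at −1.50 and CCL21 at −3.80, and among the 7 libraries at −0.74 and −4.65.

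The second comparison asked whether sets of genes for cell types and pathways differ between the groups. The lowest scores in radiation-recurrent relative to de novo tumors were those of T cells, cytotoxic lymphocytes, antigen presentation, the type I interferon response, plasma cells and checkpoint genes. Every one of the 14 T cell, 19 antigen presentation, 22 interferon and 7 plasma cell genes tested had a negative log2 fold change, as did 11 of 12 cytotoxic and 11 of 13 checkpoint genes. Genes of a list can vary together over the same tumors, so these signs are not separate observations. Of 42 lists, 0 passed after adjustment over the lists, and these 6 had an unadjusted p under 0.05 (exact permutation test, two-sided, 13884156 assignments).

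The T cell score averaged −0.71 ± 0.92 (SD, n = 8) in radiation-recurrent and 0.23 ± 0.75 (SD, n = 25) in de novo tumors, a difference of −0.93 (exact permutation p = 0.00682, adjusted p = 0.253), and 6 of the 8 radiation-recurrent tumors lay below the de novo median. Of its genes, 0 passed over all genes tested and 9 passed as lower when adjusted over the list alone, which takes no account of how the list was chosen. CD8A, the alpha chain of the cytotoxic T cell coreceptor, averaged 3.74 ± 4.58 against 18.7 ± 22.7 CPM (log2 fold change −2.32, SE 0.75, edgeR adjusted p over all genes 0.449), and CD8B, its beta chain, averaged 0.882 ± 1.06 against 4.70 ± 6.46 CPM (−2.41, SE 0.86, edgeR adjusted p 0.543). Without radiation-recurrent 8, which had the highest T cell score of the 8 (0.80), the T cell list passed, with a difference of −1.14 (exact permutation p = 0.00112, adjusted p = 0.0469). No list passed when another of the 8 was left out. The smallest adjusted p of any list (exact permutation test) then ranged from 0.0524 without radiation-recurrent 6 to 0.479 without radiation-recurrent 7. The T cell difference was −0.99 among the 26 libraries (exact permutation p = 0.0210) and −1.12 among the 7 (exact permutation p = 0.114, of 35 assignments).

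The cytotoxic lymphocyte score differed by −0.86 (exact permutation p = 0.0126, lower in 6 of 8 tumors), with 0 of 12 genes passing over all genes and 0 adjusted over the list alone. Its granzyme gene GZMK averaged 1.11 ± 1.38 against 6.69 ± 10.6 CPM, a log2 fold change of −2.59 (SE 0.92), and the granule protein gene NKG7 averaged 3.20 ± 4.22 against 13.9 ± 23.3 CPM, a log2 fold change of −2.12 (SE 0.83). The checkpoint list differed by −0.65 (exact permutation p = 0.0336, lower in 6 of 8 tumors), with 0 genes passing either way, and its inhibitory receptors LAG3 and BTLA stood at −1.88 (SE 0.78) and −1.72 (SE 0.75). The plasma cell list, with 7 of its 12 fixed genes tested, differed by −0.72 (exact permutation p = 0.0361, lower in 6 of 8 tumors) and also had 0 genes passing either way. JCHAIN, which joins immunoglobulin polymers, averaged 19.97 ± 31.5 against 113 ± 169 CPM, and the B lineage coactivator POU2AF1 averaged 2.64 ± 2.71 against 8.74 ± 9.86 CPM. Within the 26 and the 7 libraries the differences were −0.995 and −0.92 for cytotoxic, −0.77 and −0.52 for checkpoint and −0.76 and −0.74 for plasma cell genes.

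The antigen presentation score differed by −0.77 (exact permutation p = 0.0182) and the type I interferon score by −0.76 (exact permutation p = 0.0309), each lower in 7 of 8 radiation-recurrent tumors. In both lists 0 genes passed over all genes or adjusted over the list alone. NLRC5, the transactivator of class I histocompatibility genes, averaged 38.7 ± 18.6 against 76.2 ± 38.5 CPM (log2 fold change −0.98, SE 0.32), and the peptide transporter TAP1 averaged 202 ± 110.3 against 394 ± 275 CPM (−0.97, SE 0.41). Among interferon-induced genes, XAF1 averaged 37.3 ± 23.5 against 88.03 ± 58.8 CPM (−1.24, SE 0.42), and OASL averaged 22.9 ± 18.98 against 80.03 ± 80.03 CPM (−1.80, SE 0.62), with 0 radiation-recurrent tumors above the de novo median. The antigen presentation difference was −0.90 among the 26 and −0.51 among the 7 libraries, and the interferon difference was −0.87 and −0.21. With a preset correlation of 0.01, limma camera called 18 lists, 15 lower and 3 higher. With an estimated correlation it called 0 (adjusted p = 0.343 for the T cell list with an estimated correlation), and limma fry called 0.

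**Figure D3:**
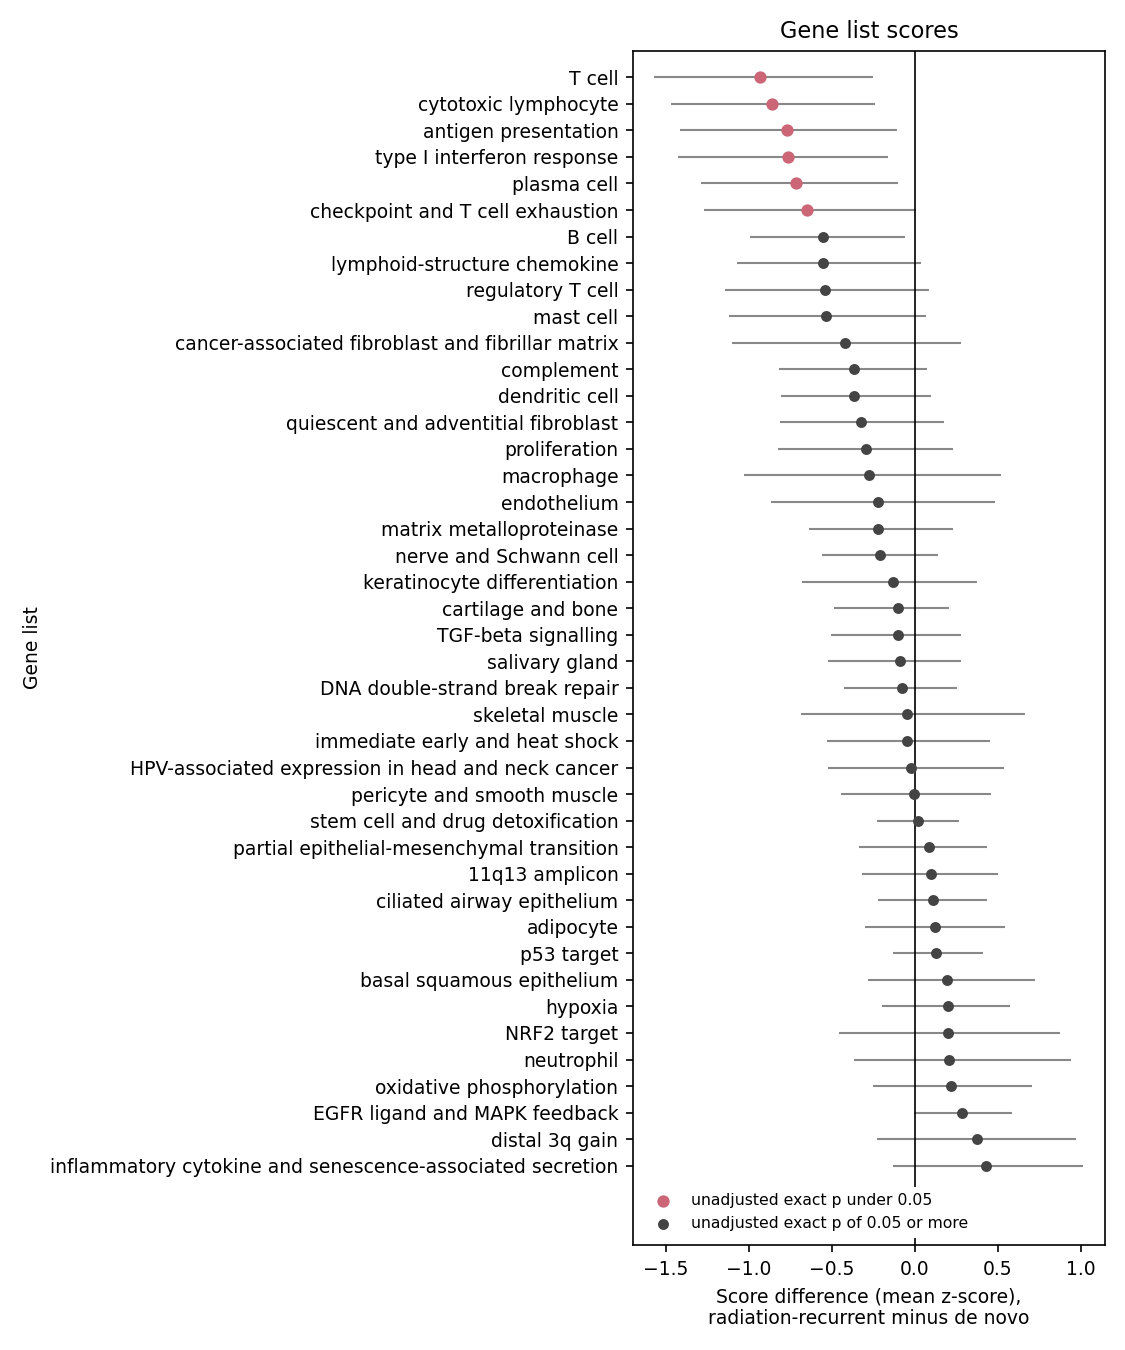
Difference of the mean list score (horizontal axis, mean z-score, radiation-recurrent minus de novo) for each of 42 gene lists, with lines for the 95 percent bootstrap interval. The 6 lists with an unadjusted exact p under 0.05 lie between −0.93 and −0.65, and 0 of the 42 passed after adjustment.

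Neutrophil and inflammatory genes mostly had positive log2 fold changes, and the macrophage score was lower, with 0 of these lists passing. All 12 neutrophil genes had positive log2 fold changes, yet the score differed by 0.21 (exact permutation p = 0.519) and was above the de novo median in 4 of 8 radiation-recurrent tumors. In this list 0 genes passed over all genes and 2 passed as higher adjusted over the list alone, the chemoattractant PROK2 (log2 fold change 3.25, SE 0.96) and G0S2 (2.07, SE 0.73), a regulator of lipid breakdown. Radiation-recurrent 8 had the highest neutrophil score, and without it PROK2 stood at −0.53, G0S2 at −0.063 and the score difference at −0.11. In DESeq2 G0S2 stood at −0.15, and in limma voom with quality weights PROK2 at −0.059. Without de novo 25 PROK2 passed over all genes (4.18, edgeR adjusted p = 0.0489). Among inflammatory cytokine and secretion genes, 18 of 19 had positive log2 fold changes, the score differed by 0.43 (exact permutation p = 0.117, above in 6 of 8 tumors), 0 passed over all genes and 5 passed as higher adjusted over the list alone. These were LIF (2.05, SE 0.57), CCL20 (1.87, SE 0.56) and, chosen after their values were seen, CXCL8 (2.23, SE 0.68), IL1A (1.43, SE 0.45) and IL1B (1.95, SE 0.67). Radiation-recurrent 8 also had the highest inflammatory score, and without it the difference was 0.24, with CXCL8 at 1.0004 and IL1B at 0.33, while without radiation-recurrent 5 CCL20 stood at 0.65. The macrophage score differed by −0.27 (exact permutation p = 0.448), while the mean log2 fold change of its genes was 0.10 and their median −0.024, 8 of 13 negative, with 0 genes passing either way. Its scavenger receptor gene MARCO stood at 1.63 (SE 0.68) and TREM2 at 0.65 (SE 0.39). Within the 26 and the 7 libraries the score differences were 0.41 and −0.35 for neutrophil genes, 0.71 (exact permutation p = 0.0387) and 0.076 for inflammatory genes and −0.27 and −0.68 for macrophage genes.

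**Figure D4:**
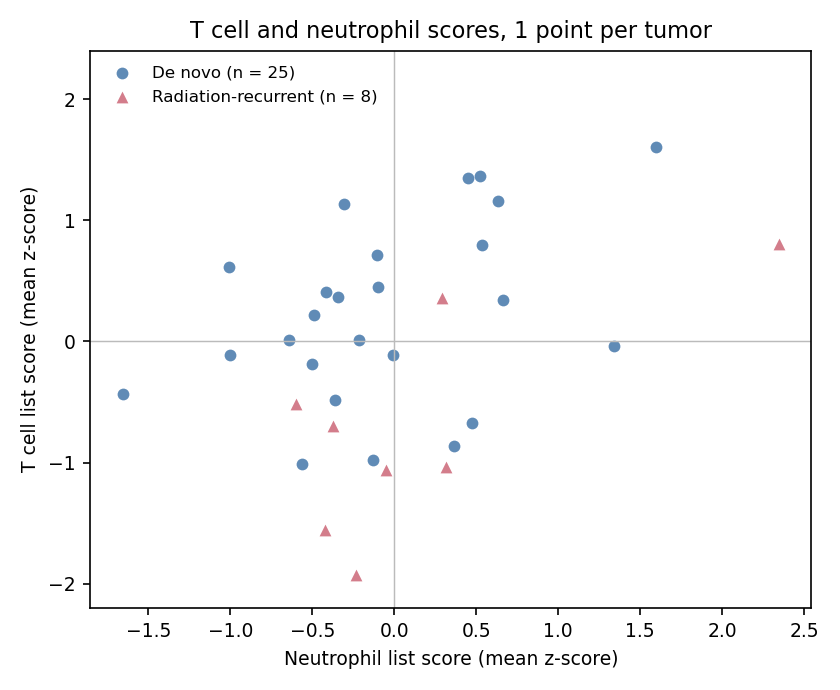
T cell list score (vertical axis, mean z-score) against neutrophil list score (horizontal axis, mean z-score), 1 point per tumor. The 8 radiation-recurrent tumors average −0.71 on the T cell axis and 0.16 on the neutrophil axis, where radiation-recurrent 8 stands at 2.34.

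Proliferation, p53 target and basal epithelium scores did not pass. All 20 proliferation genes had negative log2 fold changes, with a score difference of −0.29 (exact permutation p = 0.345, lower in 6 of 8 tumors) and 0 genes passing over all genes or adjusted over the list alone. MKI67, the Ki-67 proliferation antigen, averaged 64.3 ± 17.3 against 106 ± 50.4 CPM (log2 fold change −0.72, SE 0.27, edgeR adjusted p = 0.605), with 0 of 8 radiation-recurrent tumors above the de novo median, and the replication factor MCM2 stood at −0.39 (SE 0.26). The p53 target score differed by 0.13 (exact permutation p = 0.326, higher in 5 of 8 tumors), with 0 of 20 genes passing either way. The death receptor TNFRSF10B (0.51, SE 0.25) was above the de novo median in 8 of 8 radiation-recurrent tumors, and ZMAT3 (0.45, SE 0.26) in 7. The basal squamous epithelium score differed by 0.20 (exact permutation p = 0.631, higher in 5 of 8 tumors), again with 0 genes passing either way. De novo 6 and 11 had the lowest basal scores, −3.79 and −1.90, against −0.82 in the next tumor, and without these 2 libraries the difference was −0.064 (exact permutation p = 0.812). The keratin gene KRT17 averaged 13700.1 ± 9676 against 6762 ± 4867 CPM (1.02, SE 0.44) and S100A2 averaged 2416 ± 1441 against 1774 ± 1171 CPM (0.45, SE 0.41). Within the 26 and the 7 libraries the differences were −0.49 and 0.42 for proliferation, 0.28 and −0.074 for p53 target and 0.0022 and 0.91 for basal epithelium genes.

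Salivary gland genes averaged higher in de novo tumors, a difference that rested on 2 libraries. All 7 tested had negative log2 fold changes, 0 passed over all genes and 3 passed as lower adjusted over the list alone, MUC5B (−7.63, SE 2.55), PRR4 (−6.60, SE 2.24) and, chosen after its values were seen, ZG16B (−4.90, SE 1.84). The mucin MUC5B averaged 0.204 ± 0.224 against 40.02 ± 151 CPM, but its medians were 0.103 and 0.140 CPM, and the salivary score was above the de novo median in 6 of 8 radiation-recurrent tumors (difference −0.087, exact permutation p = 0.887). That difference was −0.26 among the 26 libraries and 0.28 among the 7. De novo 20 and 12 had salivary scores of 3.10 and 2.49, and the next de novo tumor 0.46. Without these 2 libraries MUC5B stood at −2.02 (SE 1.24), PRR4 at 0.12 (SE 0.40), ZG16B at −0.62 (SE 0.79) and the score difference at 0.21 (exact permutation p = 0.335). In DESeq2 PRR4 stood at 0.13.

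Genes fixed for report whatever their value also did not pass in edgeR. EGFR, the epidermal growth factor receptor, averaged 291 ± 129.6 CPM (SD, n = 8) against 291 ± 410.1 CPM (SD, n = 25), a log2 fold change of 0.0036 (SE 0.50), which was −0.0070 under RLE and −0.0040 under upper-quartile scaling. Its medians were 293 and 184 CPM, with 7 of 8 radiation-recurrent tumors above the de novo median. EGFR stood at 0.43 with the kind of library as a covariate, −0.29 among the 26 libraries and 1.91 among the 7. The cell cycle inhibitor CDKN2A averaged 45.2 ± 58.2 against 43.4 ± 68.4 CPM (0.056, SE 1.01), but stood at −1.18 in limma voom, −1.02 with quality weights and −0.58 in the Wilcoxon test. With the kind of library as a covariate CDKN2A stood at −0.090, among the 26 libraries at 0.61 and among the 7 at −2.68. CDKN1A averaged 362 ± 159 against 331 ± 154 CPM (0.13, SE 0.28). The checkpoint ligand CD274 averaged 12.6 ± 18.9 against 16.3 ± 17.2 CPM (−0.37, SE 0.62), and the regulatory T cell factor FOXP3 3.33 ± 3.63 against 7.19 ± 5.95 CPM (−1.11, SE 0.57, edgeR adjusted p = 0.807). Collagen COL1A1 stood at −0.42 (SE 0.53), keratin KRT5 at 0.18 (SE 0.49) and TGFB1 at −0.26 (SE 0.30). Among the 7 libraries CDKN1A stood at −0.96, CD274 at 1.06 and TGFB1 at 0.046, and with the basal epithelium score as a covariate KRT5 stood at −0.13. Exons of ACOT11, JCHAIN, MCM2, TNFRSF10B, FOXP3 and TGFB1 overlap exons on the opposite strand, and KRT5, KRT17 and PRR4 belong to families with similar sequences, so their counts are uncertain.

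The third comparison set library depth and composition side by side, as a check on RNA quality. Of 5 measures, 0 passed after adjustment (exact permutation test, two-sided, smallest adjusted p = 0.996). Mitochondrially encoded genes took 5.42 ± 1.46 percent of counts in radiation-recurrent (SD, n = 8) and 7.15 ± 10.8 percent in de novo tumors (SD, n = 25, exact permutation p = 0.746), with 56.7 percent in de novo 3, and without de novo 3 and 24 that difference was 0.327 percentage points. Ribosomal protein genes took 4.76 ± 0.918 against 4.43 ± 1.15 percent (exact permutation p = 0.468), the 50 most abundant genes 21.5 ± 3.20 against 22.2 ± 9.36 percent (exact permutation p = 0.856), and 16349 ± 204 against 16249.5 ± 278 genes were detected (exact permutation p = 0.361). Mean totals were 30.8 ± 4.55 M against 48.2 ± 113 M counts (exact permutation p = 0.996), but without de novo 3 and 24 they were higher in the radiation-recurrent libraries by 4.70 M (exact permutation p = 0.0137, adjusted p = 0.0685), and the medians differed by 6.65 M in the same direction (exact permutation p = 0.0387, adjusted p = 0.193). Within the 26 libraries the totals differed by 3.79 M and the mitochondrial share by 0.616 percentage points, and within the 7 by −132 M and −15.9 percentage points.

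The fourth comparison asked whether one category of tumor is more varied, and the fifth whether group is a main axis of variation. Mean pairwise distance over the 1000 most variable genes was 0.625 among radiation-recurrent and 0.584 among de novo tumors (difference 0.0401, permutation p = 0.685, two-sided, 100000 random assignments). The difference was 0.0181 among the 26 libraries and −0.0722 among the 7. Of 10 principal components of those genes, component 5, which carried 5.34 percent of the variance, differed between the groups (23.7 percent of its variance explained by group, exact permutation p = 0.00415, adjusted p = 0.0415), with 7 of 8 radiation-recurrent tumors on the same side of the de novo median. On the same coordinates group explained 24.1 percent of component 5 among the 26 libraries (exact permutation p = 0.0106, adjusted p = 0.106) and 13.2 percent among the 7 (exact permutation p = 0.429). With 500 genes component 5 also passed (31.1 percent explained by group, adjusted p = 0.00667, 8 of 8 tumors on 1 side). With 3000 genes no component passed (smallest adjusted p = 0.112). The kind of library explained 23.7, 21.3 and 34.7 percent of components 1, 2 and 3, of which group explained 0.0432, 1.23 and 0.373 percent. Across all 528 pairs of libraries, 0 held identical counts, and the highest correlation of log2 CPM was 0.937.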

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

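The tests of whether 1 tumor carried each call, of other tissue, skeletal muscle or immune cells in those tumors, of T cell against neutrophil scores and of the genes called without 4 de novo libraries were chosen only after the result was seen.

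Among 92 values looked at in the 8 radiation-recurrent tumors, 9 had 1 tumor far from the others, measured as its gap to the nearest tumor divided by the whole range. Chance gives about 1 in 20 for independent values that were not picked. Many of the genes here were named for their p in these same tumors, and some lists share genes. The 9 therefore cannot be set against that rate. The list of HPV-associated expression was left out of this look, a choice made for privacy after its values were seen. The gap was 0.572 for RNF182 and 0.722 for STC1, both highest in radiation-recurrent 5, and 0.529 for EGFR, lowest in radiation-recurrent 8. Radiation-recurrent 8 was highest for the neutrophil score (0.689), and radiation-recurrent 4 for the skeletal muscle score (0.609) and the share of mitochondrial counts (0.577). Radiation-recurrent 7 was lowest for the cartilage and bone score (0.619) and the partial epithelial-mesenchymal transition score (0.688). Radiation-recurrent 1 was highest for the share of counts in the 50 most abundant genes (0.594).

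Of the 7 genes higher in radiation-recurrent tumors, 7 lost the call without their own highest tumor, which was picked by its value, and a change in single recurrent tumors may account for DIRAS3, RNF182 and STC1 (log2 fold changes without it 0.84, SE 0.62, 0.43, SE 0.72, and −0.35, SE 0.47), as a hypothesis, while NELL1 (3.80, SE 0.87), ULBP1 (2.21, SE 0.65), ODAPH (1.66, SE 0.68) and SCN9A (1.18, SE 0.64) stay open. Chance cannot be excluded for the count: 55 of 100 random splits, the real one included here and below, gave at least the real 7 genes. The highest other split gave 1236 and the median other split 8, which points to a structure of the samples. Nor can chance be excluded for the 10 genes with the kind of library as a covariate (16 of 100 splits, highest other 420, median other 1). The same holds for the 38 among the 26 libraries (6 of 100 splits, highest other 318, median other 1). Given the lower medians, the kind of library may be part of that structure. Single splits still gave high counts, and other causes were not tested. Of the 4 tumors that carried the calls, 0 scored above every de novo tumor on any of 6 lists for other tissues, but radiation-recurrent 4, which carried ODAPH, had a skeletal muscle score of 1.98 and an adipocyte score of 0.95, below de novo 11 alone (2.30 and 1.10), so other tissue stays open, as does the share of immune cells, since with the T cell, B cell and macrophage score as a covariate 1 of the 7, NELL1, passed, though a median of 69.8 percent of the 7 log2 fold changes was left. With the HPV-associated score as a covariate 3 of the 7 passed, so what that score measures stays open too. NELL1, ULBP1, DIRAS3, RNF182 and STC1 passed with the kind of library as a covariate (5 of the 7) and with the skeletal muscle score (5 of the 7), which argues against each as the whole cause for those genes. SCN9A (3.45, SE 0.68) hardly moved with the kind of library (3.29, SE 0.70) or muscle (3.43, SE 0.70), with an edgeR adjusted p of 0.0573 and 0.0672, and passed among the 26 libraries (4.04), while for ODAPH (5.04, SE 0.79, with the kind 3.17, SE 0.92, with muscle 2.89, SE 0.73) both stay open.

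The T cell, cytotoxic, antigen presentation, interferon, checkpoint and plasma cell scores were lower in radiation-recurrent tumors without passing the adjusted test. Of each difference, 79.99 percent or more was left after the kind of library was regressed out, which argues against it as the whole cause. After the squamous epithelium score 95.4 percent was left, and after the mitochondrial share 95.6 percent (smallest of the 6 lists each). That score and share differed little between the groups (exact permutation p = 0.631 and 0.746), so regressing them out could remove little. It shows only that these 2 measures did not account for the differences, and leaves the share of epithelium and RNA quality undecided. The T cell minus neutrophil score differed by −1.14 between radiation-recurrent and de novo tumors (exact permutation p = 0.00131), but this pair was picked after the scores were seen and excludes nothing, and the B cell (−0.55), regulatory T cell (−0.54), mast cell (−0.54), dendritic cell (−0.36) and macrophage (−0.27) scores were lower too without passing, so a loss of all leukocytes stays open. Chance stays open for the scores, and a smaller lymphocyte share after radiation is a candidate explanation that these data did not test.

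Without de novo 3, 6, 11 and 24, 127 genes were called, and 1 of 100 random splits, the real one, gave as many (highest other 119). This setting leaves libraries with a high MT-ND6 share among the radiation-recurrent tumors alone, while the random splits scattered them. The splits therefore cannot tell a difference between tumor groups from the kind of library, and chance is not excluded. For the 1462 genes at an unadjusted p under 0.05, 21 of the 100 splits gave as many. Of the 126 higher genes, 94.4 percent were also higher in the 4 libraries left out, against 50.3 percent of all genes, and 67.5 percent overlapped exons on the opposite strand, against 20.2 percent. Genes opposite an abundant partner were higher in the 7 libraries with a high MT-ND6 share by 1.20 more (median log2 difference) than genes with no such overlap. These values are consistent with reads counted from both strands in those 7 libraries, which hold 3 radiation-recurrent tumors, as the source of most of the 126. A difference between the tumor groups in the remaining genes was not tested.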

How the results depend on the processing

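Tests that use the kind of library, leave out named de novo libraries or mitochondrially encoded genes, thin de novo 24 or use the neutrophil score were chosen only after the result was seen. No paired analysis was possible because each tumor came from a different patient. The count of 7 genes stayed within 1.5 times under RLE and upper-quartile factors, robust=FALSE, the fold minimum, the epithelium, muscle, neutrophil and kind covariates, thinning, the loss of overlapping or mitochondrially encoded genes, and without de novo 3 and 24. It was 47 with no filter, 3 with a CPM of at least 1 in at least 8 libraries, 21 in DESeq2 (1 shared), 0 in limma voom (922 at an unadjusted p under 0.05), 3 with quality weights (0 shared) and 0 in the Wilcoxon test (798 unadjusted). It was 1 with the T cell, B cell and macrophage covariate, 3 with the HPV-associated covariate, 36 with 2 surrogate variables, 38 among the 26 libraries, 0 among the 7, where fewer tumors were compared, 11 without de novo 6 and 11, 5 without de novo 12 and 20 (STC1 at 3.29 and SCN9A at 3.36 no longer passed) and 127 without de novo 3, 6, 11 and 24. Leaving out 1 de novo tumor gave 6 to 9 genes and 1 radiation-recurrent tumor 5 to 15, with 14, 14 and 15 without radiation-recurrent 1, 4 and 6. Of the 42 lists, 0 to 1 passed when 1 radiation-recurrent tumor was left out (T cell, without radiation-recurrent 8) and 18 in camera with a correlation of 0.01. In other settings 0 passed. The 1 component past the threshold became 0 with 3000 genes (smallest adjusted p = 0.112), among the 26 (0.106) and among the 7 (0.286). Except for the 7 libraries, the cause was not tested.

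The 7 libraries hold neither radiation-recurrent 5, highest of its group for RNF182 and STC1, nor radiation-recurrent 8, highest for the neutrophil score. Directions turned as follows, as log2 fold changes for genes and differences otherwise, and the cause was not tested. Among the 7 libraries with a high MT-ND6 share, −2.42 for RNF182, −0.85 for STC1, −1.11 for PROK2, −1.60 for G0S2, 0.068 for PRR4, 0.30 for MCM2, −1.06 for MARCO, −2.68 for CDKN2A, 1.06 for CD274, −0.96 for CDKN1A, 0.046 for TGFB1, −0.091 for NOTCH3, −0.82 for CXCL8, −0.34 for IL1B, 1.72 for ZG16B, 2.45 for CXCL10, 3.49 for CXCL11, 2.62 for KRT10, 0.074 for ACOT11, −0.35 for neutrophil score, 0.28 for salivary gland score, 0.42 for proliferation score, −0.074 for p53 target score and −0.0722 for the difference in spread. In DESeq2, −0.37 for STC1, −0.15 for G0S2, 0.13 for PRR4 and −0.0070 for EGFR. In limma voom with quality weights, −0.059 for PROK2 and −1.02 for CDKN2A. Without de novo 12 and 20, 0.12 for PRR4, −0.029 for EGFR and 0.21 for salivary gland score. In limma voom, −0.0015 for TREM2 and −1.18 for CDKN2A. In the Wilcoxon rank-sum test, −0.034 for TREM2 and −0.58 for CDKN2A. With RLE factors, −0.0070 for EGFR. With upper-quartile factors, −0.0040 for EGFR. With a CPM of at least 1 in at least 8 libraries, −0.0016 for EGFR. With the basal squamous epithelium score as a covariate, −0.14 for EGFR and −0.13 for KRT5. With the T cell, B cell and macrophage score as a covariate, −0.33 for EGFR, −0.11 for CDKN2A, 0.13 for CD274, −0.18 for KRT5 and 0.37 for CXCL11. With 2 surrogate variables, −0.020 for EGFR, −0.085 for CDKN2A, −0.073 for KRT5, 0.15 for CXCL11 and 0.056 for KRT10. Among the 26 other libraries, −0.29 for EGFR, 3.79 for total counts (M), 2.28 for the share of the 50 most abundant genes (percentage points) and 0.616 for the mitochondrial share (percentage points). Without de novo 3 and 24, −0.078 for EGFR, 4.70 for total counts (M), 0.956 for the share of the 50 most abundant genes (percentage points) and 0.327 for the mitochondrial share (percentage points). Without de novo 6 and 11, −0.10 for EGFR, −0.057 for CDKN2A and −0.064 for basal squamous epithelium score. Without de novo 3, 6, 11 and 24, −0.17 for EGFR, −0.0094 for CDKN2A and −0.091 for basal squamous epithelium score. With mitochondrially encoded genes left out, −0.0067 for EGFR. With the kind of library as a covariate, −0.090 for CDKN2A. With genes of opposite-strand overlap left out, −0.0059 for CDKN2A. With medians, 6.65 for total counts (M) and 0.415 for the mitochondrial share (percentage points). Leaving out 1 tumor of either group at a time gave 3.80 to 7.02 for NELL1, 2.21 to 5.29 for ULBP1, 1.66 to 5.22 for ODAPH, 0.84 to 4.99 for DIRAS3, 0.43 to 4.96 for RNF182, −0.35 to 3.56 for STC1, 1.18 to 3.68 for SCN9A, −1.36 to −1.08 for MOV10, −0.53 to 4.18 for PROK2, −0.063 to 2.50 for G0S2, −0.16 to 0.44 for EGFR, −0.57 to 0.44 for CDKN2A, −0.21 to 0.36 for KRT5, −0.021 to 0.23 for CDKN1A, 0.83 to 1.93 for CD55, −4.41 to 0.014 for CXCL10, −5.88 to 0.17 for CXCL11 and −3.48 to 0.23 for KRT10. List scores were recomputed only without each of the 8 radiation-recurrent tumors, which gave −1.14 to −0.81 for T cell score and −0.11 to 0.31 for neutrophil score. Of 2656 other values of the 46 named genes, 1035 kept direction and side of the threshold under other settings and 1461 with 1 tumor left out, 53 and 18 kept direction and no longer passed, and 6 and 2 passed newly. Of the list scores 176 kept both under other settings and 1, T cell minus neutrophil among the 7 libraries, no longer passed. Depth limited genes with few counts, and NELL1 and BCO1 had too few to be tested among the 7 libraries. ODAPH, MUC5B, GRP, NELL1 and RNF182 did not reach a CPM of 1 in 8 libraries. ACOT11, TGFB1, FOXP3, JCHAIN, MCM2 and TNFRSF10B gave no value without overlapping genes.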

Other observations

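The p-values here come from the comparisons above and their alternatives, and test no explanation. The lists and genes singled out were chosen only after the result was seen, and adjustment over a list alone takes no account of that. Other immune cell lists had lower scores in radiation-recurrent tumors without passing. The B cell score differed by −0.55 (exact permutation p = 0.0607, lower in 7 of 8 tumors), the regulatory T cell score by −0.54 (p = 0.0744), the mast cell score by −0.54 (p = 0.0959) and the dendritic cell score by −0.36 (p = 0.190), with 0 genes passing over all genes or adjusted over the list alone in edgeR and 3 B cell genes lower at an unadjusted p under 0.05, against 0 in the other 3 lists. The chemokines of lymphoid structures differed by −0.55 (exact permutation p = 0.0654), with 0 genes passing over all genes and 2 lower adjusted over the list alone, CCL21, which draws T cells to lymphoid tissue (−3.87, SE 1.13, edgeR adjusted p over all genes 0.368 and 0.0125 adjusted over the list alone), and CCL5 (−2.14, SE 0.64, edgeR adjusted p over all genes 0.397 and 0.0125 adjusted over the list alone). CCL5, a chemokine made by activated T cells, passed as lower over all genes in DESeq2 (adjusted p = 0.0399), as did CCL21 and the interferon-induced chemokines CXCL10 (−3.71, adjusted p = 0.0189) and CXCL11 (−4.58, adjusted p = 0.00398). In edgeR CXCL10 stood at −0.69 and CXCL11 at −0.43, and without radiation-recurrent 6 at −4.41 and −5.88. The DESeq2 values, where outlying counts can be replaced, lay nearer to those without radiation-recurrent 6.

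The complement score differed by −0.36 (exact permutation p = 0.129), while CD55, which protects cells from complement, was the 1 gene of the list to pass, as higher, in that list (1.77, SE 0.38, edgeR adjusted p over all genes 0.0831 and 0.000784 adjusted over the list alone). CD55 passed over all genes in DESeq2 (1.76, adjusted p = 0.0189) and in edgeR with no filter, with the kind of library as a covariate (1.81, adjusted p = 0.0279), among the 26 libraries (2.17, adjusted p = 0.0153), without de novo 3, 6, 11 and 24, and without de novo 23 or radiation-recurrent 1, 4 or 6 (adjusted p = 0.0350, 0.0275, 0.0389 and 0.0468), but without radiation-recurrent 5 it stood at 0.83 (edgeR adjusted p = 0.967). These fits share most of their tumors and are not separate evidence for CD55. In the pericyte and smooth muscle list (difference −0.0053, exact permutation p = 0.983) the 1 gene to pass in that list was NOTCH3, a receptor of vascular mural cells (1.45, SE 0.45, edgeR adjusted p over all genes 0.421 and 0.0327 adjusted over the list alone), at 0.41 without radiation-recurrent 5. The 22 other lists had 0 genes passing over all genes or adjusted over the list alone in edgeR, with 6 members higher and 4 lower at an unadjusted p under 0.05, and their score differences, with exact permutation p, were EGFR ligand and MAPK feedback 0.29 (p = 0.142), quiescent and adventitial fibroblast −0.33 (p = 0.195), cancer-associated fibroblast and fibrillar matrix −0.42 (p = 0.225), distal 3q gain 0.38 (p = 0.236), nerve and Schwann cell −0.21 (p = 0.281), matrix metalloproteinase −0.22 (p = 0.372), oxidative phosphorylation 0.22 (p = 0.395), hypoxia 0.20 (p = 0.485), endothelium −0.22 (p = 0.521), NRF2 target 0.20 (p = 0.529), adipocyte 0.12 (p = 0.563), cartilage and bone −0.10 (p = 0.606), ciliated airway epithelium 0.11 (p = 0.651), TGF-beta signalling −0.10 (p = 0.665), keratinocyte differentiation −0.13 (p = 0.683), DNA double-strand break repair −0.079 (p = 0.706), partial epithelial-mesenchymal transition 0.089 (p = 0.721), 11q13 amplicon 0.10 (p = 0.753), stem cell and drug detoxification 0.022 (p = 0.879), immediate early and heat shock −0.044 (p = 0.881), skeletal muscle −0.045 (p = 0.908) and HPV-associated expression in head and neck cancer −0.023 (p = 0.934). Of their 300 members DESeq2 called 2, both lower, the metalloproteinase MMP11 (−2.45, adjusted p = 0.0343) and the keratin KRT10 (−3.16, adjusted p = 0.0480), which stood at −2.41 and −0.44 in edgeR, KRT10 at −3.48 without radiation-recurrent 2. The direction of 3 of these scores turned among the 26 libraries and of 4 among the 7. The score, the median and the mean log2 fold change differed in sign for the nerve and Schwann cell, matrix metalloproteinase, macrophage, hypoxia, ciliated airway, partial epithelial-mesenchymal transition, 11q13, stem cell, skeletal muscle and pericyte lists.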
